A study of Mus musculus with 2 samples.

How the data were processed

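Single-cell RNA-seq of the whole thymus was available for 2 libraries, 1 from WT and 1 from Cd226KO C57BL/6 mice of 5 weeks, made with GEXSCOPE kits per the labels. Each library came as a deposited table of raw UMI counts per gene and cell, which the authors made from reads aligned with STAR 2.7.5a and assigned to genes with featureCounts 1.6.2, per the submitters' processing notes. The notes name both GRCh38 and GRCm38, while the gene symbols are of mouse. The rule by which cells were called is not stated. All values were checked to be whole numbers of 0 or above. The WT table lists 19799 genes and that of Cd226KO lists 19558, each gene found in at least 5 cells of its own table, so a gene absent from a table may be under that limit. Only the 18699 genes in both tables were compared, and the genes in 1 table alone held 0.018% and 0.016% of UMIs. Symbols were matched to GENCODE M21 (18386 genes, 98.3%) for positions and exon lengths.

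Cells with fewer than 200 genes or more than 20% mitochondrial UMIs were removed, which took 10 WT and 12 Cd226KO cells. Doublets were scored per library with Scrublet in scanpy 1.11.5 at a rate of 5%. Its automatic threshold marked 1 WT and 2 Cd226KO cells, so a score above 0.25 was used instead, chosen after seeing the scores, and 795 (2.69%) and 771 (2.72%) cells were removed. In each library 1 cell with more than 5% haemoglobin UMIs was set aside, a limit chosen after seeing the data. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 with seed 1 gave the clusters, with no correction between libraries. Clusters were named from 23 marker lists, with at least 3 markers found, and shown by their 10 leading genes. A second clustering left out the 56 leading genes that differed between the libraries. The lists, filters, naming rule and alternatives, other than those said to be chosen or added later, were fixed before the data were examined.

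UMIs were summed over the cells of a class and library and divided by the class total (CPM). Log2 ratios are Cd226KO over WT with 0.5 UMI added to each sum, and genes with 50 or more UMIs over both libraries were compared in classes of at least 200 cells per library. Intervals at the 95% level are exact conditional intervals for ratios, exact Poisson intervals for levels and Clopper-Pearson intervals for shares. Share differences have Newcombe intervals, and list medians have intervals from 500 Poisson draws. No test was made, since each group is 1 library. Named genes are the 12 highest and 12 lowest in resting double-positive-like and single-positive-like cells, and 4 each in other classes, at least 1.5-fold apart with an interval that leaves out 0 and ranked by the bound nearer 0, beside the 4 members of a list furthest from 0. Predicted genes named Gm or Rik, sex-linked genes and haemoglobin genes were left out of that ranking, and genes that lead a cluster of a class were not given as results in it. Pooled non-thymocytes were not compared gene by gene because their mix differs. Where a group had 0 UMIs, a fold was given only for Cd226, against a floor of 3 UMIs over the group. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, which left medians of 655 and 663 genes, and 573 WT cells were too shallow.

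The 19 fixed gene lists were read as medians over measured members and placed among 10000 random lists matched on mean expression. The trend of the ratio over exon length was removed in 20 bins as an alternative. Tested on simulated data with 9698 genes, of which 200 differed 2-fold, 95.5% of intervals held the true ratio, 94.5% of those genes were recovered by the naming rule, and 1.12% of unchanged genes passed it. The simulated counts were Poisson draws with counting error only, as the intervals assume. These values are therefore not error rates for other differences between libraries, such as free RNA or the exon length trend. A list of raised genes lay at percentile 100 and a list of unchanged genes at 29.8. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.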

Results

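Single-cell RNA-seq of the thymus was deposited for 2 groups of 5-week-old C57BL/6 mice, wild type (WT) and Cd226-deficient (Cd226KO), with 1 GEXSCOPE library per group. Cd226 encodes a co-stimulatory receptor of T and NK cells that binds Pvr and Nectin2. The labels do not state how many animals went into a library or which part of Cd226 is deleted. The WT table held 29559 cells and 78721253 UMIs, with a median of 1876 UMIs and 1026 genes per cell. The Cd226KO table held 28373 cells and 77430494 UMIs, with a median of 1810 UMIs and 1013 genes per cell. The lowest number of UMIs in a listed cell was 980 in WT and 1021 in Cd226KO, and the median mitochondrial share of UMIs was 3.77% and 3.88%. After filtering and removal of called doublets, 28753 WT and 27589 Cd226KO cells were clustered together. Because each genotype is 1 library, no test across samples was possible and the difference has no replicate check. Intervals are 95% intervals and cover counting error only. They are exact for UMI sums (Poisson), ratios of sums (conditional) and single shares (Clopper-Pearson). Those of share differences (Newcombe) and of list medians (500 Poisson draws) are approximate.

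The 29 clusters were named from marker genes fixed before the data were examined, and the names are rebuilt ones because no annotation of cells was used here. Resting double-positive-like cells, thymocytes between the pre-TCR burst and selection, were led by Rag1, Spo11 and Trp53inp1. The 6 cycling double-positive-like clusters were led by replication and mitosis genes such as Ccne2, Esco2, Nusap1 and Ube2c, beside Rag2 in 1 of them. TCR-signalled-like cells, thymocytes under selection, were led by Cd5, Itm2a, Tox and Nab2. The single-positive-like classes were led by Zbtb7b and Izumo1r (CD4), by Itgae and Nkg7 (CD8), by S1pr1 and Klf2 (mature) and by Ms4a4b, Igfbp4 and Ccr7 (cycling mature). Double-negative-like clusters were led by Hes1 and Il2ra or by Cpa3 and Plac8, and the NK, NKT or innate lymphoid-like cluster by Cxcr6, Xcl1 and Il18r1. Plasma cell-like, macrophage-like, dendritic-like, granulocyte-like, thymic epithelial-like and fibroblast-like clusters were pooled as non-thymocytes. The unnamed clusters, with 15.1% of cells in each library, included cluster 4 (Ung, Srm and Cdc6), cluster 8 (Ccnb1, Plk1 and Myc) and cluster 13 (Tnfrsf9, Nr4a3 and Cd200). These leading genes describe the clusters and are not results between the genotypes.

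Cd226 transcripts were much rarer in the Cd226KO library in every T-lineage class, and least so in NK, NKT or innate lymphoid-like cells. Cd226 (chromosome 18, 89176967 to 89272229, GRCm38) had 1024 UMIs in all WT cells and 79 in all Cd226KO cells. Scaled to 1000000 UMIs (CPM), these sums are 13.6 (12.7 to 14.4) and 1.06 (0.84 to 1.32), 12.7-fold (10.2 to 16.3) lower in Cd226KO. CD8 single-positive-like cells held the most Cd226 in WT, at 121 (109 to 135) CPM, against 13.8 (8.82 to 20.5) in Cd226KO. CD4 single-positive-like cells had 89 UMIs in WT and 0 in Cd226KO, at least 26-fold lower against a floor of 3 UMIs (the exact interval starts at 20.7-fold), and double-positive-like cells had 91 and 0, at least 28.4-fold lower by that floor (from 22.7-fold). TCR-signalled-like cells had 71 UMIs in WT and 4 in Cd226KO, or 34.9 (27.3 to 44.1) and 1.26 (0.345 to 3.24) CPM.

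NK, NKT or innate lymphoid-like cells kept 38 Cd226 UMIs in Cd226KO against 82 in WT. That was 32.9 (23.3 to 45.2) against 71.7 (57 to 89) CPM, a log2 ratio of -1.11 (-1.72 to -0.55). With every cell thinned to 1000 UMIs, a Cd226 UMI was found in 1.68% (1.53 to 1.84) of WT cells and 0.149% (0.107 to 0.202) of Cd226KO cells, and without thinning in 2.95% and 0.236%. In the NK, NKT or innate lymphoid-like cluster the thinned shares were 7.74% (5.48 to 10.6) and 4.40% (2.81 to 6.53). In non-thymocytes they were 0.304% (0.063 to 0.885) and 0.168% (0.004 to 0.934). Plasma cell-like cells had 0 Cd226 UMIs in both libraries, and macrophage-like cells had 2 in each. Thinning left out 573 WT cells and 0 Cd226KO cells. UMIs from an undeleted part of the gene would count in these sums, since the labels do not place the deletion.

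**Figure D1:**
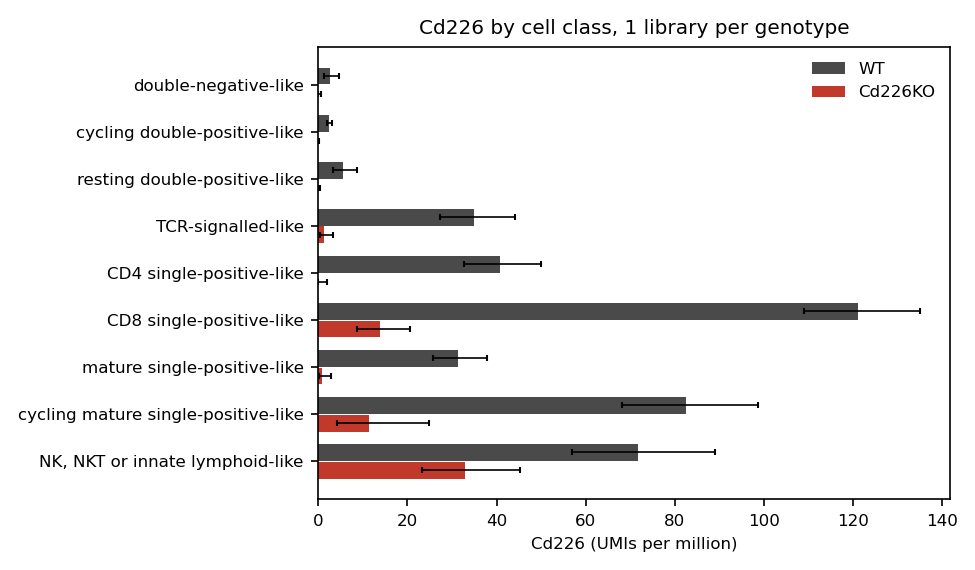
Cd226 level (horizontal axis, CPM) in each cell class of the WT (grey) and Cd226KO (red) libraries, 1 library per genotype, with exact 95% Poisson intervals as error bars. CD8 single-positive-like cells had 121 in WT and 13.8 in Cd226KO, and NK, NKT or innate lymphoid-like cells had 71.7 and 32.9.

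The makeup of the thymus differed most in double-positive-like cells, where resting cells were more and cycling cells less frequent in Cd226KO. Resting double-positive-like cells made up 9.70% (9.36 to 10.0) of WT cells and 21.9% (21.4 to 22.4) of Cd226KO cells, a ratio of 2.26. Cycling double-positive-like cells, clustered without the 56 leading genes that differed between the libraries, made up 36.7% (36.1 to 37.3) and 27.9% (27.3 to 28.4). All double-positive-like cells together were closer in the libraries, at 48.7% in WT and 51.0% in Cd226KO, or 46.9% and 50.3% without those leading genes. TCR-signalled-like cells were 5.07% (4.82 to 5.33) in WT and 7.75% (7.43 to 8.07) in Cd226KO, a ratio of 1.53. Among cells of 2000 or more UMIs, a setting added after seeing the data, the share of all double-positive-like cells was instead lower in Cd226KO by -3.56 points. The resting share by itself stayed higher in Cd226KO at that limit, at 0.430% in WT and 3.17% in Cd226KO. The resting cells lie close to the lowest number of UMIs of the tables, with medians of 1156 UMIs in WT and 1254 in Cd226KO, so the rule that chose the barcodes, which the labels do not state, can set their share.

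Single-positive-like cells were less frequent in Cd226KO, at 15.5% against 20.8% in WT. The difference of -5.33 (-5.97 to -4.70) points became -5.41 points after clustering without those 56 genes, and was -2.01 points among cells of 2000 or more UMIs. In the clustering without those genes, CD8 single-positive-like cells were 5.56% (5.30 to 5.83) in WT and 3.40% (3.19 to 3.62) in Cd226KO, CD4 single-positive-like cells 5.64% (5.37 to 5.91) and 4.91% (4.66 to 5.17). Shares within a library depend on each other, so the larger resting double-positive-like share (10.2% and 22.4%) by itself lowers all others. Small decreases such as that of CD4 single-positive-like cells cannot be told apart from this. Mature single-positive-like cells were 7.43% and 6.07%, and their cycling counterparts 1.75% and 0.58% (0.50 to 0.68). Double-negative-like cells, the earliest thymocytes, were 4.73% (4.48 to 4.98) in WT and 6.37% (6.09 to 6.67) in Cd226KO. Gamma-delta T-like cells were alike within counting error, at 0.55% and 0.51%, and NK, NKT or innate lymphoid-like cells were 1.65% (1.51 to 1.81) and 1.90% (1.74 to 2.07).

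Non-thymocytes were 3.41% of WT and 2.13% of Cd226KO cells in the same clustering. Monocyte or granulocyte-like cells, the class that differed most in ratio, were 111 cells (0.39%, 0.32 to 0.46) in WT and 13 cells (0.05%, 0.03 to 0.08) in Cd226KO. Macrophage-like cells were 1.02% and 0.64%, conventional dendritic-like cells 0.77% and 0.45%, plasma cell-like cells 0.63% and 0.47%, and plasmacytoid dendritic-like cells 0.35% and 0.25%. Thymic epithelial-like cells were 0.23% and 0.17%. The intervals of the plasma cell-like, plasmacytoid dendritic-like and thymic epithelial-like shares overlapped between the libraries. Of these 3, the interval of the difference, Cd226KO minus WT, held 0 only for thymic epithelial-like cells (-0.13 to 0.02 points). It was -0.28 to -0.03 for plasma cell-like and -0.19 to -0.01 for plasmacytoid dendritic-like cells. Fibroblast-like cells were 9 in WT and 27 in Cd226KO. Unnamed cells were 17.28% and 15.95%. Tissue digestion sets how many epithelial, stromal and myeloid cells are freed, so these shares need not be those of the organ.

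**Figure D2:**
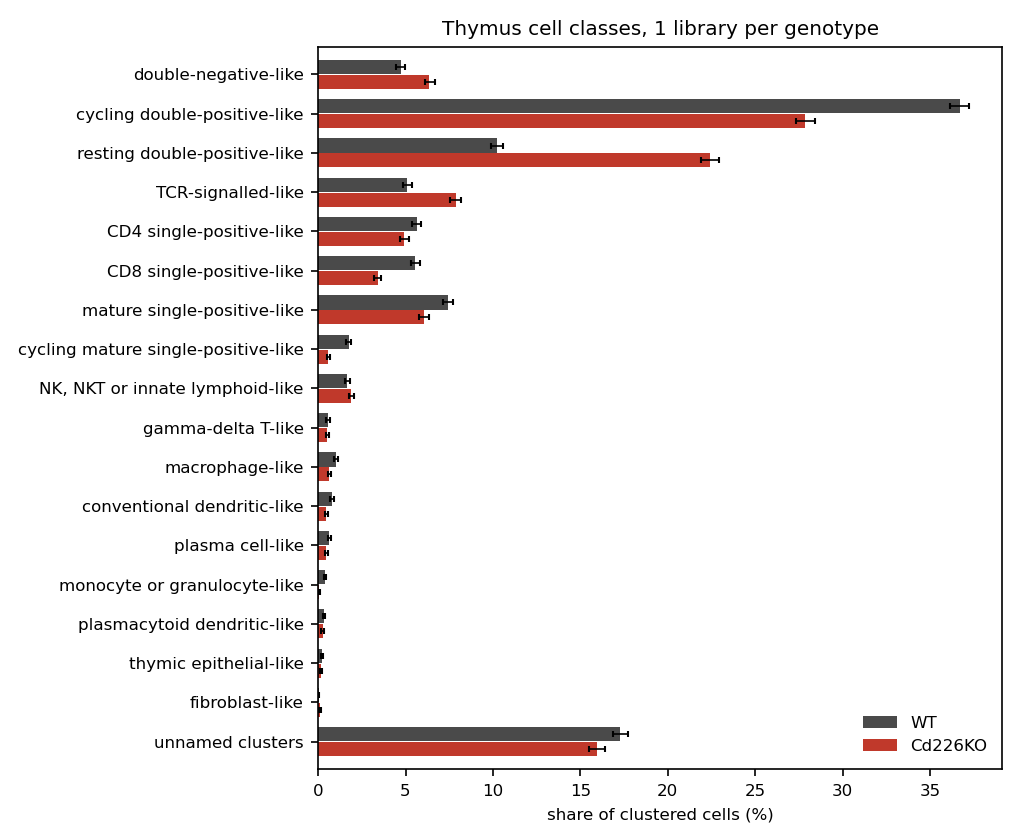
Share of clustered cells (horizontal axis, percent) in each cell class of the WT (grey) and Cd226KO (red) libraries, clustered without the 56 leading genes that differed, with exact 95% Clopper-Pearson intervals as error bars. Resting double-positive-like cells were 10.2% in WT and 22.4% in Cd226KO, and cycling double-positive-like cells 36.7% and 27.9%.

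The UMIs of the co-receptor genes were also read, in cells of the thymocyte and unnamed clusters. Among these cells thinned to 1000 UMIs, 20.9% of WT and 26.5% of Cd226KO cells had a UMI of Cd4 together with 1 of Cd8a or Cd8b1. Cells with Cd8a or Cd8b1 alone were 56.5% and 50.3%, cells with Cd4 alone 3.84% and 3.98%, and cells with neither 18.7% and 19.2%. Without thinning, the shares with both were 35.6% and 42.1%. Cd4 has few UMIs per cell, so many double-positive thymocytes fall among the cells with Cd8 alone. A Cd4 UMI was also found in more Cd226KO cells within classes, in 51.7% and 55.1% of resting and 26.4% and 28.1% of cycling double-positive-like cells, so these shares are not a separate count of double-positive thymocytes.

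In resting double-positive-like cells, Cd226KO had more transcripts of the TCR-induced nuclear receptor Nr4a1, of the ERK phosphatase Dusp5 and of Gzma, a protease of cytotoxic granules, and far fewer of the electron carrier Cyb5a. Nr4a1 was at 94.0 CPM in WT and 215 in Cd226KO, a log2 ratio of 1.19 (1.02 to 1.37). Dusp5 was at 53.1 and 123 (1.21, 0.99 to 1.45), and Gzma at 102 and 231 (1.17, 1.01 to 1.34), beside 3695 and 3528 in gamma-delta T-like cells. Gzma also leads the unnamed clusters 4 and 8, so free RNA from other cells can add to its UMIs in resting cells. Cyb5a was at 1454 and 394 (-1.88, -1.95 to -1.82). Thinned to 1000 UMIs per cell, 8.20% (7.17 to 9.32) of WT and 15.8% (14.8 to 16.7) of Cd226KO resting cells had an Nr4a1 UMI, whereas in non-thymocytes the shares were 16.5% and 15.7%. For Dusp5 the thinned shares were 5.03% (4.22 to 5.94) and 10.5% (9.72 to 11.3) in resting cells, and 5.36% and 6.40% in non-thymocytes. A Cyb5a UMI was found in 72.1% of WT and 29.4% of Cd226KO resting cells, and in 27.9% and 24.9% of non-thymocytes. None of these 4 genes was particular to resting cells. Over 17 large clusters, Nr4a1 (median log2 ratio 0.64), Dusp5 (0.99) and Cyb5a (-1.71) kept their direction in all 17, and Gzma (0.65) in 16.

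Other genes higher in Cd226KO resting cells have varied functions. Rab4a, a small GTPase of endosomal recycling, had 5 UMIs in WT and 136 in Cd226KO, a log2 ratio of 3.37 (2.25 to 5.15). Acpp, an acid phosphatase, had 5 and 94 (2.84, 1.70 to 4.63), and Wdfy1, an endosomal protein, 15 and 118 (1.67, 0.93 to 2.60). The peptide transporter gene Slc15a2 was at 31.0 and 77.9 CPM (1.32, 1.03 to 1.64), the neuron navigator gene Nav2 at 17.1 and 46.5 (1.43) and Eps8l1, of an actin-regulating family, at 7.54 and 21.2 (1.47). Papss2, which makes the sulfate donor of the cell, was at 20 and 47.7 (1.24), and Tle6, a Groucho-type co-repressor gene, at 6.96 and 23.7 (1.74).

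Genes lower in Cd226KO resting cells also had varied functions. Fgf13, a non-secreted fibroblast growth factor homologue, had 63 UMIs in WT and 24 in Cd226KO, a log2 ratio of -2.64 (-3.40 to -1.95), and Igf2bp3, a fetal RNA-binding protein, 69 and 47 (-1.81, -2.38 to -1.26). Ly6k, a GPI-anchored surface protein gene, was at 108 and 30.7 CPM (-1.81, -2.05 to -1.58), and Adam12, a metalloprotease gene, at 55.7 and 23.5 (-1.25, -1.54 to -0.95). The calcium channel gene Cacna1e (-1.70), the DNA repair gene Mgmt (-1.66), the Myc relative Bmyc (-1.43) and Pydc3, a pyrin-domain gene (-2.16), were also lower.

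Granulocyte genes and some antibody genes, which thymocytes do not make, also differed in resting cells. Ighg2b had 0 UMIs in WT and 147 in Cd226KO resting cells, and in plasma cell-like cells it was at 546 and 27779 CPM. S100a8 was at 47.6 and 4.36 CPM (-3.43, -4.01 to -2.92), beside 595 and 68.6 over all cells. S100a9 (-3.32) and the antimicrobial peptide gene Camp (-3.51) were lower in the same way. The antibody genes were not alike, with Igkc at 76.9 and 117 CPM (0.60, 0.41 to 0.81), Jchain at a ratio of 0.43 (-0.16 to 1.09) and Igha at 34.2 and 28.9 (-0.25, -0.57 to 0.09), although Igha was at 43519 and 64095 in plasma cell-like cells. Thinned, an S100a8 UMI was in 4.45% of WT and 0.381% of Cd226KO resting cells, close to the 4.06% and 0.478% of all cells.

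Of 9698 genes with 50 or more UMIs over both libraries, 745 were at least 1.5-fold apart in resting cells, 505 higher and 240 lower in Cd226KO, a rule of size and not a test. Counting error alone would put 204.0 genes that far apart. Of the 391 higher and 182 lower genes whose interval also left out 0, 200 and 72 had their highest level in non-thymocytes, by any margin. The share of such genes among all 9698 was not counted. Cyb5a is among them, at 1213 and 850 CPM in fibroblast-like cells, only 1.5-fold its level in resting cells. These genes therefore cannot all be read as free RNA. Without all genes highest in non-thymocytes, a setting added after seeing the data, 375 remained. With 200 or more UMIs required the count was 234. The split moved to 419 higher and 295 lower with median-ratio scaling, and to 1327 and 2173 with 1 UMI in each library.

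**Figure D3:**
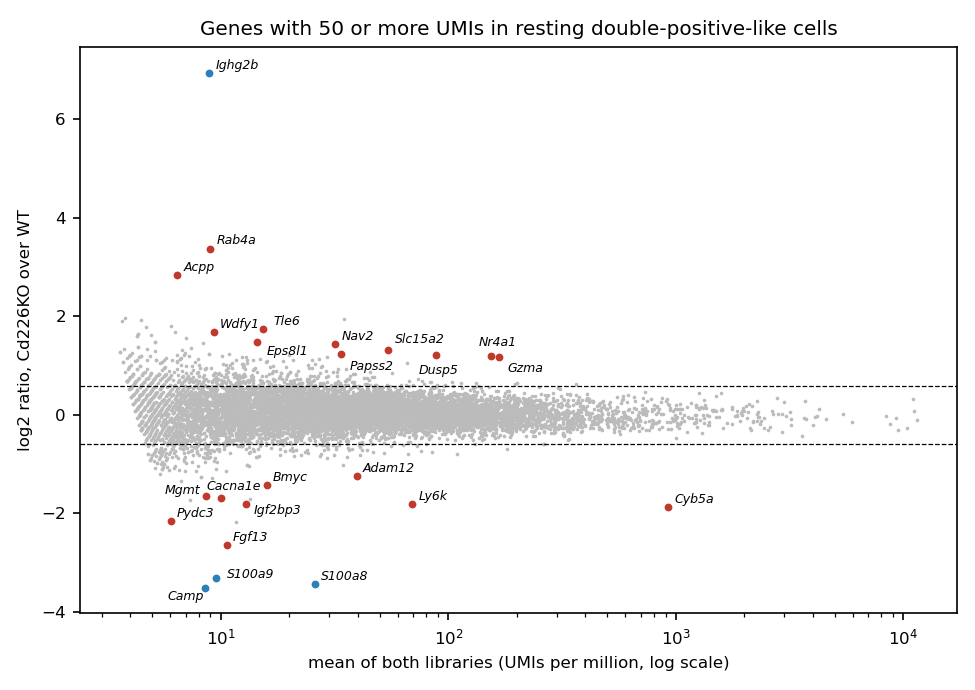
Log2 ratio, Cd226KO over WT (vertical axis), against the mean level of both libraries (horizontal axis, CPM, log scale) for each gene with 50 or more UMIs in resting double-positive-like cells, 1 library per genotype. Red and blue points are named genes, blue those at least 20-fold higher in non-thymocytes, and dashed lines mark 1.5-fold; Cyb5a lies at -1.88 and Nr4a1 at 1.19.

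Each gene list was compared with 10000 random lists matched on mean expression, and its percentile is the share of those with a lower median. In resting double-positive-like cells, interferon response genes were higher in Cd226KO as a group, with a median log2 ratio of 0.24 over 20 measured genes (percentile 99.5) and 17 above 0. Without the parts of the cluster rich in nuclear RNA, a setting added after seeing the data, their median was 0.11 (percentile 87.9), inside the range of random lists. Xaf1 had a ratio of 1.09 (0.58 to 1.68), Ifi203, a DNA-sensing family gene, 1.04 (0.79 to 1.31), and the transcription factors Irf1 and Irf9 0.86 (0.51 to 1.24) and 0.72 (0.33 to 1.16). Genes induced by TCR signals had a median of 0.13 (0.03 to 0.26), with 10 of 13 above 0 and a percentile of 88.3, inside the range of random lists. Beside Nr4a1, the I-kappa-B family gene Nfkbid (0.66, 0.12 to 1.26) and Ikzf2 (0.37, 0.14 to 0.61) were higher, while the interval of Rel (0.44) held 0. Genes of the TCR signalling machinery had a median of 0.10 (percentile 95.7), with 17 of 24 above 0, among them Plcg1 (0.41, 0.21 to 0.62) and the kinase gene Fyn (0.25, 0.02 to 0.49). After removal of the trend of the ratio over exon length, that list's median was 0.03 (percentile 87.0), and without the parts rich in nuclear RNA 0.04 (percentile 80.9).

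Pro-apoptotic genes as a group did not stand apart in resting cells, with a median of -0.01 (-0.07 to 0.10, percentile 22.8) over 25 genes, or -0.02 over the 24 other than Trp53inp1, which leads the cluster. Pmaip1, which encodes the BH3-only protein NOXA, had a ratio of 1.23 (0.60 to 1.98) on 22 and 126 UMIs. Its highest level is in conventional dendritic-like cells, so free RNA can add to its UMIs in both libraries. Cd74 (-0.76) and H2-Aa (-0.82), also highest in those cells, were however lower in Cd226KO resting cells, so such RNA need not raise the ratio. Pmaip1 was higher in all 17 large clusters (median log2 ratio 1.02), so its difference was not particular to resting cells. It lies 22.7 Mb from Cd226, and an effect of DNA beside the targeted gene cannot be told apart. In the pro-apoptotic list Apaf1, of the apoptosome, had 0.39 (0.04 to 0.76). Pro-survival genes had a median of 0.11 (percentile 83.3), with Akt1 at 0.58 (0.27 to 0.90) and Mcl1 at 0.34 (0.21 to 0.48). Maturation and egress genes had 0.15 (percentile 95.5), including B2m (0.47, 0.40 to 0.54) and Nfkb1 (0.51, 0.23 to 0.82). Glucocorticoid response genes also had 0.15 (percentile 90.6), including the clock gene Per1 (0.75, 0.45 to 1.07). V(D)J recombination genes other than Rag1 had -0.02 (percentile 32.6), with Dclre1c (Artemis) at 0.47 and Lig4 at 0.36.

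Cell cycle and respiration genes were lower in Cd226KO resting cells, in which parts rich in nuclear RNA were 2.01 and 6.92 times as frequent as in WT. G2 and M phase genes had a median of -0.28 (percentile 0.0), with 34 of 47 below 0, such as Cdc20 (-0.84, -1.23 to -0.43) and Birc5 (-0.67, -0.97 to -0.36), and S phase genes -0.10 (percentile 0.4), with 31 of 39 below 0, such as Rrm2 (-0.72, -0.99 to -0.44). Nuclear genes of oxidative phosphorylation had -0.19 (percentile 0.0), with 21 of 22 below 0, such as Ndufb8 (-0.51, -0.66 to -0.35) and Sdhb (-0.38, -0.49 to -0.26). Without the exon length trend that median was -0.09 (percentile 5.0). Without the parts rich in nuclear RNA, G2 and M phase genes had -0.15 (percentile 0.4), oxidative phosphorylation genes -0.14 (percentile 0.9), S phase genes -0.11 (percentile 3.4) and class II genes -0.19 (percentile 12.7), the latter 2 inside the central 95% of random lists. Class II antigen presentation genes had -0.38 (percentile 0.1), led by H2-Aa (-0.82) and Cd74 (-0.76), whose level in conventional dendritic-like cells was 45933 and 40515 CPM, and those cells were less frequent in Cd226KO. Glycolysis genes had -0.03 (percentile 30.2), immediate early and dissociation stress genes 0.00 (percentile 48.0), the 4 measured cytotoxic effector genes -0.31 (percentile 3.0, Gzma alone above 0) and the 5 regulatory T programme genes 0.15 (percentile 75.4).

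The ratio of a gene also followed its exon length, in resting cells with a Spearman correlation of 0.32 across genes, which are not independent replicates. Genes at the short end of exon length, up to 2333 bases, had a median log2 ratio of -0.11, and those at the long end, from 7551 bases, 0.17. In single-positive-like cells the correlation was 0.38, with medians of -0.10 and 0.24.

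In single-positive-like cells, the aldo-keto reductase genes Akr1c12 and Akr1c13, the Qa-2 genes H2-Q7 and H2-Q6 and Rab4a were higher in Cd226KO. The lists of cell cycle genes were lower. Akr1c12 had 32 UMIs in WT and 159 in Cd226KO, a log2 ratio of 2.75 (2.22 to 3.37), and Akr1c13 was at 14.8 and 41.3 CPM (1.48, 1.19 to 1.77). Akr1c18, a progesterone-degrading enzyme gene, and Myo6, a myosin gene, lead the CD4 cluster and are therefore given in TCR-signalled-like cells, where they had 4 and 57 UMIs (3.04, 1.76 to 5.12) and 17 and 115 UMIs (2.08, 1.38 to 2.95). H2-Q7 and H2-Q6, class Ib genes of the Qa-2 antigen, were at 126 and 325 CPM (1.36, 1.26 to 1.46) and at 7.01 and 26.6 (1.92, 1.52 to 2.34). Rab4a was at 3.51 and 21.3 (2.59, 2.07 to 3.18), Wdfy1 at 3.61 and 11.3 (1.64), Eps8l1 at 3.91 and 12 (1.61) and Klhl4, of the Kelch family, at 1.6 and 6.75 (2.04).

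Cd226 itself led the lower genes of single-positive-like cells, at 66.1 (61.2 to 71.4) and 4.55 (3.13 to 6.38) CPM, a log2 ratio of -3.84 (-4.41 to -3.36). Igf2bp3 was at 17.5 and 3.99 (-2.11, -2.75 to -1.56), Fgf13 at 25 and 7.58 (-1.72, -2.17 to -1.30), Fam174b at 5.11 and 1.10 (-2.14) and the centromere gene Cenpm at 33.6 and 12.9 (-1.37, -1.72 to -1.04). Pydc3 leads the cycling mature cluster, and in mature single-positive-like cells of cluster 3 it was at 250 and 76.8 (-1.70, -1.92 to -1.50). The ribosomal pseudogene Rpl17-ps5 had 106 and 10 UMIs (-2.88). Genes read as free RNA differed here too, with Ighg2b at 4 and 101 UMIs, Ighg2c at 12 and 51, S100a8 at 445 and 41, Ngp at 88 and 7, Camp at 130 and 14 and S100a9 at 124 and 17. The macrophage gene Apoe was at 35.1 and 13.1 CPM (-1.42), beside 308 and 134 over all cells. Of 10289 genes, 898 were at least 1.5-fold apart, 553 higher and 345 lower in Cd226KO, against 133.9 from counting error alone.

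The lowest lists in single-positive-like cells were those of the cell cycle. G2 and M phase genes had a median of -0.56 (percentile 0.0), with 46 of 51 below 0, among them Ccnb2 (-0.95, -1.14 to -0.77), Hmmr (-0.88) and Ube2c (-0.84, -0.95 to -0.72). S phase genes had -0.48 (percentile 0.0), with 38 of 41 below 0, among them Rrm2 (-0.88, -1.03 to -0.73) and Exo1 (-1.02, -1.79 to -0.33). Without the cycling mature cluster 17 the medians were -0.23 and -0.30, each at percentile 0.0. Oxidative phosphorylation genes had -0.22 (percentile 0.0) with 20 of 22 below 0, or -0.14 (percentile 3.3, inside the central 95% of random lists) without the exon length trend, and class II genes -0.24 (percentile 0.2), with Cd74 at -0.57. Of the receptor family and ligands of Cd226, Crtam was at -0.77 (-1.40 to -0.20), Pvr at 0.40 (0.18 to 0.61) and Cd96 at 0.03 (-0.08 to 0.14).

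In the pooled single-positive-like cells, the lists of TCR signalling machinery, immediate early and stress, glucocorticoid response and maturation genes lay above the central 95% of random lists, and those of TCR response, interferon response, regulatory T and pro-survival genes inside it. Without the exon length trend, and with members that lead a cluster, the latter 4 lay above it, at percentiles 99.9, 100, 99.7 and 98.9. TCR signalling machinery had a median of 0.18 (percentile 99.9), with Fyn at 0.54 (0.43 to 0.64), Cblb at 0.45 and Plcg1 at 0.43, and 0.06 (percentile 98.7) without the exon length trend. TCR response genes other than Itm2a had 0.20 (percentile 96.2), with 16 of 19 above 0, such as Nr4a2 (0.78, 0.29 to 1.29), Irf4 (0.65, 0.19 to 1.12) and Nr4a1 (0.62, 0.54 to 0.69). Within the clusters that list had a median of -0.06 in CD4, 0.05 in CD8 and 0.08 in mature single-positive-like cells, below its pooled median. Immediate early and dissociation stress genes had 0.23 (percentile 99.9), with 13 of 17 above 0, and 0.10 (percentile 90) in CD4 single-positive-like cells. Glucocorticoid response genes had 0.31 (percentile 99.5), with Per1 at 0.90 (0.68 to 1.13) and the IL-7 receptor gene Il7r at 0.47 (0.38 to 0.55), but 0.24 (percentile 97.0, inside the central 95%) without cluster 17 and 0.15 (percentile 82.3) in CD4 single-positive-like cells. Maturation and egress genes other than cluster-leading ones had 0.18 (percentile 98.3), against 0.02 (percentile 52.2) for the whole list in CD4 single-positive-like cells, and interferon response genes 0.17 (percentile 96.6), with Mx1 at 0.70 (0.23 to 1.18), though -0.09 in CD4 single-positive-like cells. Regulatory T programme genes had 0.32 (percentile 97.3), with the inhibitory receptor gene Ctla4 at 1.12 (0.73 to 1.53) and Foxp3 at 0.37 (-0.23 to 0.97), but within the clusters 0.07 in CD4, 0.08 in CD8 and 0.20 in mature single-positive-like cells. Pro-survival genes had 0.19 (percentile 94.2), with Mcl1 at 0.57 (0.46 to 0.69) and Bcl2a1b at -0.90 (-1.39 to -0.44). Pro-apoptotic genes had 0.03 (percentile 18.7), with Bcl2l11 (BIM) at 0.58 (0.37 to 0.80), V(D)J genes 0.13 (percentile 65.9), glycolysis genes -0.01 (percentile 32.7) and cytotoxic effector genes 0.04 (percentile 30.1), with Klrd1 at -0.78 and Gzma at 0.68.

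Cycling double-positive-like cells had more Nr4a1, at 66.6 and 133 CPM (1.00, 0.92 to 1.09), and more of the heat shock genes Hspa1b (1.87) and Hspa1a (1.75, 1.51 to 2.01) in Cd226KO. Eps8l1 had 36 and 173 UMIs (2.64, 2.13 to 3.22) and Rab4a 36 and 149 (2.43, 1.91 to 3.01), while Cd226 had 72 and 0. Antibody genes Ighg2b (5 and 224 UMIs) and Ighg2c (33 and 128), and the granulocyte genes S100a8 (1022 and 129), Camp (315 and 32) and Ngp (170 and 17), are genes of plasma or granulocyte cells and were read as free RNA. Glucocorticoid response genes had a median of 0.27 (percentile 99.8) with 10 of 10 above 0, interferon response genes 0.24 (percentile 99.5) with 18 of 20, immediate early and stress genes 0.18 (percentile 99.8) and TCR signalling machinery 0.13 (percentile 99.7), with Cd28 at 0.39 (0.33 to 0.46). Without the exon length trend the median of the signalling machinery was 0.03 (percentile 97.8). TCR response genes had 0.11 (percentile 73.1). S phase and G2 and M phase genes, without those that lead the clusters, had 0.05 (percentile 93.1) and 0.03 (percentile 95.6). Class II genes had -0.50 (percentile 0.0). Of 11584 genes, 666 were at least 1.5-fold apart, 403 of them higher, with 132.1 from counting error alone.

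In TCR-signalled-like cells, Nr4a1 was at 356 and 601 CPM (0.76, 0.63 to 0.88) and Nr4a3 at 21.2 and 34.5 (0.69, 0.18 to 1.25), whereas the early activation marker Cd69 was at 349 and 252 (-0.47, -0.62 to -0.32). TCR response genes other than those that lead the cluster had a median of 0.17 (percentile 93.1), with 8 of 12 above 0. TCR signalling machinery had 0.16 (percentile 99.9), with Rasgrp1 at 0.40 (0.26 to 0.55), and pro-survival genes 0.21 (percentile 97.9), with the apoptosis inhibitors Xiap at 0.64 (0.29 to 1.02) and Birc2 at 0.60 (0.25 to 0.97). Without the exon length trend, the whole signalling machinery list had 0.09 (percentile 99.1). Nav2 was at 12.8 and 44.0 CPM (1.76) and Eps8l1 at 5.41 and 20.9 (1.89), while Fgf13 (29.5 and 6.01, -2.27), Cyb5a (773 and 283, -1.45) and S100a8 (42.3 and 10.8, -1.96) were lower. S phase, G2 and M phase and oxidative phosphorylation genes had -0.21, -0.20 and -0.17, each at percentile 0.0, and class II genes -0.71 (percentile 0.0). Without the exon length trend the oxidative phosphorylation median was -0.05 (percentile 25.1). Of 8197 genes, 681 were at least 1.5-fold apart, against 215.3 from counting error alone.

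Double-negative-like cells of Cd226KO had more Hspa1b, at 14.4 and 55.9 CPM (1.94, 1.56 to 2.37), Akr1c12, at 8.38 and 36.5 (2.11, 1.61 to 2.68), and Wdfy1, at 2.56 and 14.1 (2.41, 1.55 to 3.52). Pro-survival genes had a median of 0.23 (percentile 99.7), with Mcl1 at 0.82 (0.62 to 1.02) and Bcl2 at 0.60 (0.44 to 0.77). Cytotoxic effector genes had 0.43 (percentile 99.7), with 4 of 6 above 0, such as Ifng at 1.24 (0.50 to 2.09), Gzmb at 1.22 (0.34 to 2.28) and Gzma at 0.54 (0.43 to 0.65), and both others below 0 with intervals that left out 0, such as Ctsw at -0.39 (-0.71 to -0.06). TCR signalling machinery had 0.15 (percentile 99.8), with the kinase genes Prkcq (0.50) and Zap70 (0.44), glucocorticoid response genes 0.21 (percentile 98.9) and interferon response genes 0.19 (percentile 99.2), although Irf7 was at -0.59 (-1.08 to -0.10). G2 and M phase genes had -0.19 (percentile 0.0), with 45 of 51 below 0, such as Dlgap5 (-0.55) and Aurkb (-0.47). The myeloid protease gene Prtn3 had 58 and 0 UMIs. The lower named genes S100a8 (170 and 20), S100a9 (64 and 8) and Camp (45 and 6), and the higher Ighg2b (1 and 68 UMIs, 5.05, 3.09 to 10.95) are genes of plasma or granulocyte cells and were read as free RNA. Of 9846 genes, 631 were at least 1.5-fold apart, against 168.1 from counting error alone. The class pools clusters 12 and 15, so a different mix of early stages cannot be separated from different levels.

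NK, NKT or innate lymphoid-like cells of Cd226KO had more transcripts of cytotoxic effector genes as a list, and of Ccl3, Ctla4 and Tnfrsf4. Cytotoxic effector genes other than the 4 that lead the cluster had a median of 0.57 (percentile 100), with 9 of 9 above 0, such as Gzmk (1.85, 1.04 to 2.81), Gzma (1.53, 1.27 to 1.80) and Ifng (1.23, 0.89 to 1.59). The chemokine gene Ccl3 was at 10.5 and 129 CPM (3.57), Ctla4 at 3.50 and 49.4 (3.66, 2.38 to 5.74), the co-stimulatory receptor gene Tnfrsf4 (OX40) at 14.9 and 86.6 (2.51, 1.79 to 3.38), and the enkephalin precursor gene Penk had 0 and 67 UMIs. A higher Ctla4 level was not particular to this cluster, as it was found in 16 of 17 large clusters (median log2 ratio 1.02). Maturation and egress genes had 0.49 (percentile 100), with Ms4a4b at 0.84 (0.73 to 0.95), TCR response genes 0.46 (percentile 99.8), with Nfkbid at 1.10 (0.70 to 1.53), Cd69 at 0.82 (0.55 to 1.09) and Id3 at -0.81 (-1.09 to -0.55), and immediate early and stress genes 0.41 (percentile 100), with Hspa1b at 2.16 (1.51 to 2.92). Pro-survival genes had 0.33 (percentile 99.3), with Bcl2 at 1.35 (0.96 to 1.77), and regulatory T programme genes 0.57 (percentile 99.8). S phase genes had -0.55 and G2 and M phase genes -0.36, both at percentile 0.0, with Cdk1 at -1.07 (-1.52 to -0.65), and glycolysis genes -0.37 (percentile 0.1), with Pgk1 at -0.75 and Ldha at -0.54 (-0.69 to -0.39). The chemokine receptor gene Ccr10 was at 70.9 and 19 CPM (-1.87, -2.65 to -1.20), Fam83a at 48.1 and 10.4 (-2.17), the lysosomal protease gene Lgmn at 53.4 and 6.93 (-2.87) and S100a8 at 42.9 and 2.60 (-3.84, -6.37 to -2.41). The cluster may hold several lymphoid kinds, so a different mix of them cannot be separated from different levels. Of 5958 genes, 1084 were at least 1.5-fold apart, against 243.0 from counting error alone.

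**Figure D4:**
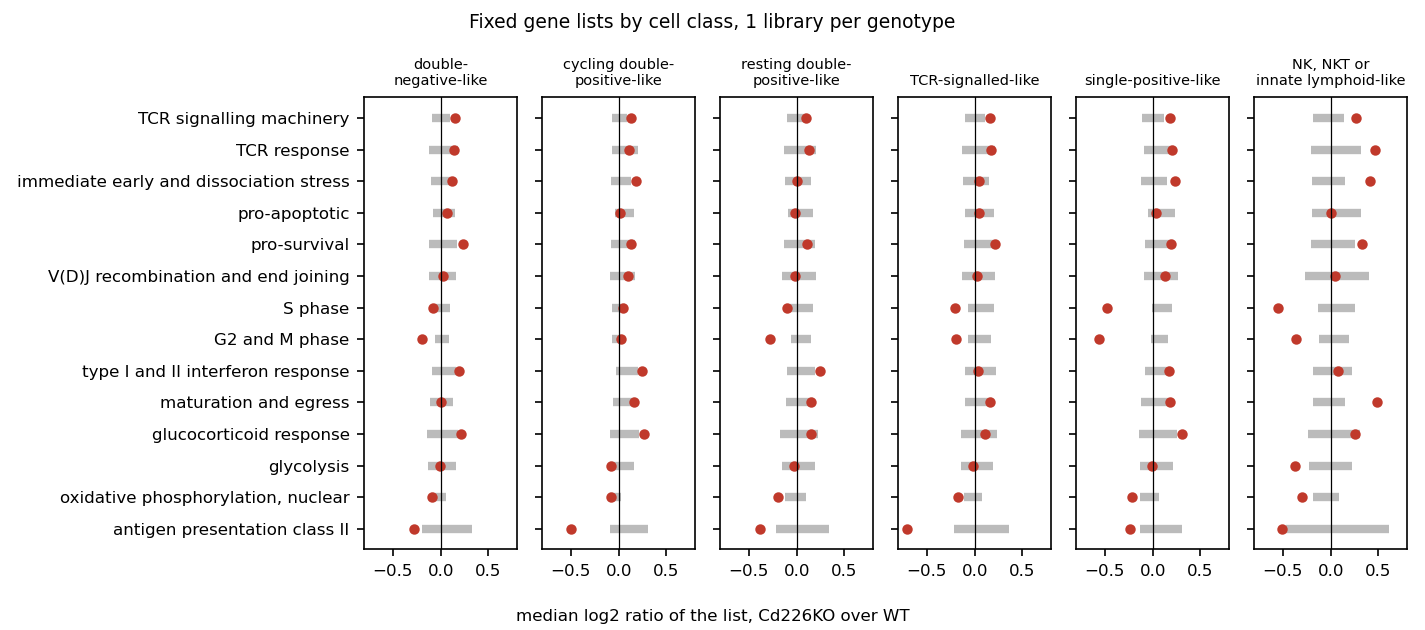
Median log2 ratio, Cd226KO over WT (horizontal axes), of 14 fixed gene lists in 6 cell classes, 1 library per genotype, without members that lead a cluster of the class; red points are the lists and grey bars the central 95% of 10000 random lists matched on mean expression. G2 and M phase genes lie at -0.56 in single-positive-like and -0.28 in resting double-positive-like cells, and interferon response genes at 0.24 in resting double-positive-like cells.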

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

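The tests of nuclear RNA, of the loss of Cd226, of DNA beside Cd226 and of free RNA were chosen after the results were seen, and those of depth, of Nnt and of mixed WT cells before. The genes used in the test of mixed WT cells were however picked from the results.

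Antibody variable segments were found outside the compared genes, since each table lists some that the other does not. The WT table alone lists 20 such segments with 1453 UMIs in 201 cells, and the Cd226KO table alone lists 24 with 5211 UMIs in 342 cells. They stand out because no comparison used them.

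Resting double-positive-like cells took 2.26 times the WT share in the Cd226KO library. Deeper Cd226KO cells passing the lowest number of UMIs are argued against as the whole reason, because the ratio was 2.20 after the UMIs of Cd226KO cells were divided by the median depth ratio of the other clusters, 1.08, and 1 lowest number of UMIs was applied (8.634% and 19.002%), and the depth ratio it would need, 1.47, lies above those of 16 other clusters (0.979 to 1.18). Damaged cells rich in nuclear RNA are argued against as the whole cause, because without the 2 parts of the cluster rich in it the ratio was 1.58 (1.46 to 1.71). Those parts were however 2.01 and 6.92 times as frequent in Cd226KO, so handling of the tissue may have added to the pattern. Loss of Cd226, with its ratio of 2.26, cannot be told apart from any other difference between 2 single libraries.

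There were 76 genes on 20 chromosomes, 38 higher and 38 lower in Cd226KO, that differed in the same direction in each of 17 large clusters with a median over these of at least 1.5-fold. Among them, by median log2 ratio, were Rab4a (2.44), Akr1c12 (2.08), Dusp5 (0.99), Nr4a1 (0.64), Hoxa7 (-2.13), Fgf13 (-2.12) and Cyb5a (-1.71). Free RNA from non-thymocytes is argued against as the whole cause, since 17.1% of them (13) were highest in non-thymocytes by 20-fold or more. DNA of another strain kept beside the targeted gene may explain Cyb5a, 4.3 Mb from Cd226, and Pqlc1 (1.04), 8.9 Mb away, and it cannot be told apart for these, as the 5 of 91 genes apart within 30 Mb (5.49%, against 2.71% of all 10667), counted without free-RNA-like genes, 3 of which (Cd74, Pdgfrb and Pmaip1) were also apart there, were more than in 89.7% of 8754 runs of as many genes elsewhere, where the highest count was 10. For C57BL/6J against C57BL/6N animals, Nnt, which carries a deletion in C57BL/6J, should be at least 2-fold apart. It had 143 and 175 UMIs, a log2 ratio of 0.31 (-0.02 to 0.64), so a 2-fold difference was not seen. The interval is however too wide to call the libraries alike, and the counts do not show positions within a gene. This explanation therefore cannot be told apart. A mixed background was not tested. Loss of Cd226 itself stays open and untested here, as does any difference of animals between the libraries.

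Cd226 UMIs were kept in the NK, NKT or innate lymphoid-like cluster of Cd226KO, with 38 UMIs in 31 cells. Free RNA is argued against, because the lower bound of the level there, 23.3 CPM, lies above the upper bound of 1.92 in CD4 single-positive-like cells of the same library. Cells of the WT library among these 31 cells are argued against by 10 genotype-marking genes. They were picked from the named genes of these data as at least 1.5-fold apart in each large cluster. Those lower in Cd226KO held 16 UMIs in the 31 cells and those higher 37. The lower genes thus made up 30.2% (18.3 to 44.3), against 80% (76.8 to 83.0) in WT and 37.3% (33.6 to 41.0) in other Cd226KO cells of the cluster. Transcripts from an undeleted part of the gene or another start site may remain in these cells, which was not tested because the counts do not show positions within a gene. Retention was not limited to this cluster. CD8 single-positive-like cells of Cd226KO held 24 Cd226 UMIs in 22 cells (13.8 CPM, 8.82 to 20.5), whereas CD4 single-positive-like cells held 0.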

How the results depend on the processing

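Clustering without the leading genes that differed, the doublet score of 0.35, cells of 2000 or more UMIs, removal of genes highest in non-thymocytes, of the length trend and of nuclear-RNA-rich cells were chosen after the results were seen. No paired analysis was possible because each group is 1 library.

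The difference in the double-positive-like share, Cd226KO minus WT, was 2.33 points and turned to -3.56 among cells of 2000 or more UMIs, a setting that removes most resting cells by construction. It was 3.50 with 20 principal components, 3.38 without the leading genes, 3.35 with a doublet score of 0.35 and 6.49 with classes from Cd4 and Cd8 UMIs, and between 2.41 and 3.03 in the 5 others of 10 alternatives, inside the counting interval of the main value (1.502 to 3.153). The single-positive-like difference, -5.33 points, was -6.36 with doublets kept, -2.01 among cells of 2000 or more UMIs and -6.33 from Cd4 and Cd8 UMIs, where it mirrors the rise of cells with both because most cells counted hold Cd8 UMIs alone, and inside its interval (-5.97 to -4.70) in 7 of 10. The double-negative-like difference, 1.45 points, was 1.83 with 20 principal components and 3.40 among cells of 2000 or more UMIs, and inside its interval (1.075 to 1.821) in 7 of 9. For these shares the cause was not tested otherwise.

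The number of genes at least 1.5-fold apart in resting double-positive-like cells, 745, was 234 with 200 or more UMIs required, 3500 with 1 UMI in each library and 375 without genes highest in non-thymocytes, since each setting changes which genes are counted. It was 543 without nuclear-RNA-rich cells, with 330 higher and 213 lower, 651 without the length trend, and between 714 and 755 in the 5 others. With median-ratio scaling, a shift of 0.040, the split of 505 higher and 240 lower genes became 419 and 295, and with 1 UMI in each library 1327 and 2173.

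Over the alternatives run, the non-thymocyte difference lay between -1.42 and -1.21 points in 9, the TCR response median between 0.05 and 0.16 in 9, the pro-apoptotic median between -0.05 and 0.06 in 9, with both signs, and the Cd226 log2 ratio between -3.72 and -3.66 in 3.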

Other observations

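Genes were compared in the unnamed clusters 4, 8 and 13. Cluster 4 had 7.06% of WT and 7.15% of Cd226KO cells, with Wdfy1 at 1.46 and 11.7 CPM (2.96), H2-Q7 at 3.9 and 20.8 (2.40), the heat shock co-chaperone gene Bag3 with 6 and 51 UMIs (2.89) and Fgf13 at 19.5 and 4.1 CPM (-2.24). Cluster 8, with 4.54% and 5.02% of cells, had Rab4a at 1.27 and 8 CPM (2.61), Hspa1a at 15.8 and 63.2, Hspa1b at 11.9 and 45.4 (1.92) and Cyb5a at 728 and 209 (-1.80). In both clusters Ighg2b was higher and S100a8, S100a9 and Camp lower in Cd226KO. Cluster 13, led by activation genes and holding 2.77% and 2.32% of cells, had H2-Q7 at 92.4 and 235 CPM (1.35), Cdk5rap1 at 9.69 and 36.7 (1.89), Pydc3 at 46.5 and 5.84 (-2.90), the replication gene Pclaf at 258 and 112 (-1.21) and Cd226 with 59 and 1 UMIs. Clusters 21 and 27 held 0.536% and 0.202% of WT cells and 0.482% and 0.091% of Cd226KO cells.

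The clusters pooled as single-positive-like cells were also read apart. CD4 single-positive-like cells had Rab4a with 7 and 53 UMIs (3.03), Akr1c12 at 5.94 and 38.1 CPM (2.64), Fgf13 at 29.7 and 4.7 (-2.59) and Igf2bp3 at 32.9 and 7.3 (-2.13). CD8 single-positive-like cells had the Qa-2 genes H2-Q6 at 13.8 and 62.5 CPM (2.16) and H2-Q7 at 209 and 545 (1.38), the ubiquitin ligase gene Znrf2 at 36.9 and 88.9 (1.27) and Pydc3 at 167 and 80.3 (-1.06). Mature single-positive-like cells of cluster 3 had Akr1c12 at 2.26 and 21.1 CPM (3.15), Akr1c18 at 5.37 and 34.8 (2.67) and H2-Q7 at 102 and 341 (1.74).

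Sex-linked and blood genes were read as checks of the animals. The Y-linked genes Ddx3y (5364 and 6722 UMIs), Eif2s3y (5197 and 5944), Kdm5d (1848 and 2238) and Uty (1225 and 1476) were found in both libraries, and Xist was listed in neither. Haemoglobin genes were low, with Hba-a1 at 1407 and 774 UMIs and Hbb-bs at 970 and 634 over all cells of the tables, before any were removed. Hba-a1 was at 17.9 and 10 CPM there, but at 0.53 and 0.322 CPM in clustered cells. Most of its UMIs therefore came from cells left out of the clusters.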
